A study of Pimephales promelas with 26 samples.

How the data were processed

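The measurements were RNA sequencing libraries from pools of 20 whole fathead minnow larvae, 5 water controls and 21 libraries from 5 measured fluoxetine concentrations. Per the labels' protocols, messenger RNA was selected by poly(A) tail and libraries were made with a directional kit, which keeps the strand. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38 and the tools kallisto and DESeq2 were used, without versions. The transcript index, its genome build and the kallisto settings are not given in the sources used here. The authors deposited kallisto's estimated counts per RefSeq transcript, which need not be whole numbers, for each library and again together for all 26 libraries. The largest difference between the 2 forms was 5e-08. The deposited TPM values, which are scaled to transcript length and to a common sum, were not tested. The deposited transcript length and effective length gave the fragment length of each library, as the median difference between them over transcripts of at least 3000 bases.

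For each concentration against water, the authors deposited a comparison table of 26962 transcripts. Per the file headers, it holds the authors' mean of normalized counts (a signal averaged over samples), their log2 fold change with its standard error, their test statistic (a score), and their p-value and adjusted p-value. These tables were compared with the tests made here and were not used in them.

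Estimated counts were rounded to whole numbers and tested per transcript as deposited. The table held 57299 transcripts, 48442 of them messenger RNA models and 8857 non-coding models. The reference gene table (assembly fPimPro1.hap1.1, which may not be the build the authors used) paired 31554 of them with a gene (55.1%), matching accessions without their version, since only 207 had the same version. These carried 82.6% of counts. Because fewer than 80% were paired, transcripts were not summed per gene, as had been laid down, so transcripts as deposited, first meant as a comparison, were tested and sums per gene were set beside them. Of the 43837 transcripts tested, 24073 (54.9%) had a symbol other than a locus number. Kallisto divides reads shared by transcripts of 1 gene or by near-identical paralogs between them, so a value for a single transcript is less certain than the sum for its gene. No coordinates are given.

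Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3, with files read by the data.table package, version 1.17.8. Low counts were removed with filterByExpr over the 6 groups, which kept 99.9% of counts, and libraries were scaled by TMM, with factors from 0.951 to 1.04. A robust quasi-likelihood model was fitted to all 26 libraries, so that groups of 3 shared the estimate of spread. Each concentration was tested against water, all 5 together by an F-test, and a slope on log2 of the concentration plus 0.1 µg/L. A transcript was called at a Benjamini-Hochberg adjusted p below 0.05 over all transcripts of that test, with no minimum fold. Tests were two-sided. The standard error of a log2 fold change was taken from the fold change and its quasi-likelihood F statistic. Levels are given as CPM with SD over libraries. The floor was 3 counts per library, and floors and the spread between counts cover counting error only, since no molecular identifiers were used.

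The 26 gene lists covered serotonin signalling, the stress axis, biotransformation and transporters, cholesterol biosynthesis, lysosome and phospholipidosis, lipid and energy metabolism, photoreceptors, circadian clock, cell cycle, p53 and apoptosis, oxidative stress, heat shock and unfolded proteins, estrogen and vitellogenesis, thyroid axis, immune response, neuropeptides, neuron, glia, skeletal and cardiac muscle, hepatocyte, exocrine pancreas and intestine, lens, erythroid cells, epidermis and ionocytes, and cartilage, bone and collagen. Each list was tested at each concentration with camera at a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over all 130 tests, of which 41 passed. With an estimated correlation 0 of the 130 passed (smallest adjusted p 0.641), and with fry, a rotation test of whether a list moves on balance one way, 0 passed. Macrophage, neutrophil and lysosome-rich enterocyte markers were added after the data had been seen.

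Benchmark concentrations came from linear, power, saturating exponential and Hill curves fitted to log2 CPM by least squares, the best taken by AIC, for transcripts with an unadjusted slope or F-test p below 0.05 and a largest group change of at least 1.5-fold. The benchmark was a move of 1 residual SD, values above the highest concentration or below 0.1 of the lowest were left out. Intervals are 95% percentile intervals over 1000 bootstrap draws of transcripts. The curve fits, the tests and camera were tested on simulated data. With 50 transcripts changed at each fold, 56% of 4-fold changes were recovered at 0.74 µg/L and at 47.2 µg/L, with 1 and 2 false calls. Linear curves made with benchmarks of 3, 10 and 30 µg/L gave medians of 2.95, 9.71 and 28.1 µg/L over 300 curves each. Other curve shapes, and benchmarks below 3 µg/L, were not simulated. In camera, a list of 40 simulated transcripts shifted by 0.5 passed, and an unshifted one of the same size did not.

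The groups, the tests, the gene lists, the other settings to be tried and the rule for named genes were chosen before the data were examined. Named were, among called transcripts with a symbol and a mean of at least 1 CPM, the 12 largest rises and falls at 47.2 µg/L and at the concentration with the most calls, and the 5 largest of each at the others. So were up to 4 members of each list with the smallest adjusted p; slc6a4a, slc6a4b and cyp1a; up to 10 transcripts with the smallest adjusted p for trend; and up to 5 trend calls with the lowest benchmark. These settings were RLE size factors, no count filter, a stricter filter (10 counts in 20 libraries), DESeq2 1.42.0, the replicate letter as a block, fits of only 2 groups, other slopes and curve settings, and leaving out each library in turn. Added after seeing the data were sums per gene, fragment length as a covariate, a fit without replicate B of both the 0.19 and 47.2 µg/L groups, which stood apart from the rest, and contrasts between exposed groups. So were the lysosome list tests without each library at 47.2 µg/L, counts of shared calls in 10 splits of the water libraries between comparisons, and counts of the libraries on the side of each list call. The labels give no batch or sequencing date.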

Results

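Gene expression was measured by poly(A)-selected RNA sequencing in whole larvae of the fathead minnow (Pimephales promelas), a small cyprinid fish used in toxicity testing. The larvae had been exposed through the water to fluoxetine, an antidepressant that blocks the serotonin transporter, from 6 h to 7 days after fertilization, and each library came from a pool of 20 larvae. The 26 libraries comprised a water control (n = 5) and 5 measured concentrations, which were 0.19 µg/L (n = 3), 0.74 µg/L (n = 5), 3.38 µg/L (n = 5), 10.2 µg/L (n = 5) and 47.2 µg/L (n = 3). The protocol describes a separate set of embryos for each replicate. The series title sets transcriptomic points of departure, the concentrations at which expression begins to change, beside adverse effects on the whole animal. Total estimated counts per library ranged from 13515500 to 27615000 (n = 26). A floor of 3 counts therefore corresponded to between 0.109 and 0.222 CPM (counts-per-million). All 46 pairs of replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 15.7, so none was taken for a library deposited again. This does not test whether the pools were independent. The fragment length implied by the deposited effective lengths ranged from 235 to 239.5 bp in water, from 248 to 258 bp at 0.19 µg/L and from 250.4 to 263 bp at 0.74 µg/L. It ranged from 222 to 242 bp at 3.38 µg/L, from 226 to 247 bp at 10.2 µg/L and from 228 to 247 bp at 47.2 µg/L.

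At 47.2 µg/L, the highest concentration, single transcripts of lysosomal and of intestinal proteins were called. The ctsla transcript (XM_039649953.1), which encodes the lysosomal protease cathepsin L, rose from 512 ± 50.5 CPM (SD, n = 5) in water to 923 ± 180 CPM (SD, n = 3). Its log2 fold change was 0.85 ± 0.15 (SE; edgeR adjusted p = 0.0269). This call held in 22 of the 26 fits that left out 1 library, and was lost without replicate A or B at 47.2 µg/L or water replicate B or E. The sum over the ctsla transcripts was also called (0.85 ± 0.15, SE; adjusted p = 0.0171). One transcript of lgmn (XM_039656403.1), which encodes the lysosomal protease legumain, rose by 0.67 ± 0.13 on the log2 scale (SE; adjusted p = 0.0469). The sum over the lgmn transcripts differed by 0.65 ± 0.14 (SE; adjusted p = 0.0574) and was not called. Those of vac14, a scaffold of the enzyme complex that makes a signalling lipid of endosomes and lysosomes, rose by 0.66 ± 0.11 (SE; adjusted p = 0.0105). The slc15a1a transcript (XM_039690752.1), which encodes the intestinal peptide transporter, fell from 69.8 ± 6.50 CPM (SD, n = 5) to 34.5 ± 9.54 CPM (SD, n = 3). Its log2 fold change was -1.02 ± 0.15 (SE; adjusted p = 0.00838). The water channel aqp8a.1 had a log2 fold change of -0.67 ± 0.13 and the gamma-glutamyltransferase ggt1b one of -0.87 ± 0.16 (SE), and both passed the test. The aqp8a.1 call held in 6 and the ggt1b call in 20 of the 26 fits that left out 1 library.

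In all, edgeR called 45 of 43837 transcripts at 47.2 µg/L, 32 of them higher and 13 lower, and 30 of the 45 carried a gene symbol. Among genes of connective tissue, the proteoglycan prelp rose by 1.17 ± 0.18 (log2, SE) and the matrix metalloproteinase mmp14b by 0.74 ± 0.14. Further transcripts that rose were those of ktn1 (1.23 ± 0.21), a kinesin receptor of the endoplasmic reticulum, hpca (1.07 ± 0.17), a neuronal calcium sensor, and slc22a16 (0.77 ± 0.07), an organic cation and carnitine transporter. The serine protease prss59 rose by 0.74 ± 0.13, the transporter gene slc35f6 by 0.74 ± 0.09, the phospholipid scramblase plscr3a by 0.74 ± 0.14 and enosf1 by 0.67 ± 0.13 (log2, SE). One transcript of mbpa, which encodes myelin basic protein, fell by 3.03 ± 0.60 on the log2 scale, whereas the sum over the mbpa transcripts differed by -0.27 ± 0.13 (adjusted p = 0.442). The slc22a16, slc35f6 and slc15a1a calls held without any 1 of the 26 libraries, and the lgmn call in 4 of those 26 fits. The enosf1 and mbpa calls held in 7 of them, the plscr3a call in 9, the mmp14b call in 11, the ktn1 and prss59 calls in 24 and the prelp, hpca and vac14 calls in 25. The count of 45 was 20, 24 and 17 without water replicates B, D and E, and 8 without replicate A at 47.2 µg/L. Which transcripts were called also changed, since 6 of the 8 calls without that replicate, 27 of the 49 without replicate B and 24 of the 38 without replicate C at 47.2 µg/L were among the 45. Without replicate A 3 calls were higher and 5 lower, and without replicate B 26 and 23. Without replicate B of both the 0.19 and 47.2 µg/L groups there were 58 calls, 25 higher and 33 lower, and 25 of the 58 were among the 45. The count was 783 with DESeq2, of which 42.8% were higher against 71.1% with edgeR, 29 with no count filter, 101 after summing transcripts per gene, and 0 by edgeR (3258 at an unadjusted p below 0.05) when only the water and 47.2 µg/L libraries were fitted. Adding the replicate letter as a block gave 182 calls at 47.2 µg/L, all 45 among them.

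The lysosome and phospholipidosis list, fixed beforehand, rose at 47.2 µg/L with a median log2 fold change of 0.30 over 72 transcripts (camera, adjusted p = 1.72e-11; adjusted p = 0.641 with an estimated correlation). The size of the rise depended on replicate A, whose mean over the list's genes lay 0.566 above the water mean (log2) against 0.195 and 0.209 in replicates B and C. Without replicate A the median was 0.19 (unadjusted p = 2.54e-06; 0.0375 with an estimated correlation), a fit added after seeing the data. Of these 72, 2 were called higher over all transcripts tested, ctsla and lgmn, while 24 were higher and 1 lower when adjusted over the list alone. The lysosomal membrane protein gene lamp1a had a log2 fold change of 0.73 ± 0.15 (SE; adjusted p = 0.0705) and ctsba, a cathepsin B gene, one of 0.78 ± 0.18 (SE; adjusted p = 0.101). When transcripts were summed per gene, 6 of 56 lysosomal genes were called higher, and 26 higher and 1 lower when adjusted over the list alone. These included the beta-galactosidase relative glb1l (0.85 ± 0.14) and the progranulin gene grnb (0.73 ± 0.14), which were named after their values had been seen. Macrophage markers, a list added after seeing the data, had a median log2 fold change of 0.38 over 22 transcripts at the same concentration, and neutrophil markers, also added, one of 0.33 over 6 transcripts. Markers of uptake in lysosome-rich enterocytes, the third added list, had a median of -0.56 over 9 transcripts.

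Photoreceptor transcripts fell at 47.2 µg/L (median -0.23, 67 transcripts, camera adjusted p = 4.17e-06), as did neuronal transcripts (median -0.18, 82 transcripts, adjusted p = 0.00146). Both had adjusted p = 0.641 with an estimated correlation. The hepatocyte list also fell (median -0.13, 58 transcripts, adjusted p = 0.00435; adjusted p = 0.664 with an estimated correlation). Adjusted over the list alone, 6 photoreceptor transcripts were lower, among them those of rcvrn2 (-0.79 ± 0.21), a recoverin that slows photoreceptor recovery, and the rod phosphodiesterase subunit pde6b (-0.48 ± 0.13). The blood clotting factor f7 (-0.68 ± 0.15, log2, SE) was lower in the hepatocyte list by the same criterion. The cartilage, bone and collagen list rose (median 0.40, 63 transcripts, adjusted p = 1.63e-06; adjusted p = 0.641 with an estimated correlation), and 3 of its transcripts were higher when adjusted over the list alone. Its mean over the list's genes lay below the water mean in replicate A (-0.05, log2) and above it in replicates B and C (0.38 and 0.58), and that of the neuron list lay above the water mean in replicate B (0.03). In the other 7 of the 9 lists that passed at 47.2 µg/L, all 3 libraries lay on the side of the call. The immune list rose with a median of 0.33 over 52 transcripts (adjusted p = 0.000146; adjusted p = 0.641 with an estimated correlation). Over all transcripts tested, the listed members called at 47.2 µg/L were ctsla, lgmn, prss59, slc15a1a and mbpa.

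Stress lists rose by smaller amounts at 47.2 µg/L, each with adjusted p = 0.641 with an estimated correlation. The heat shock and unfolded protein list had a median of 0.16 over 61 transcripts (camera adjusted p = 0.000590). Of these, 2 were higher when adjusted over the list alone, ddit3 (0.85 ± 0.18), a transcription factor of the unfolded protein response, and the small heat shock protein hspb8 (0.59 ± 0.14). Neither passed over all transcripts tested, with adjusted p of 0.0647 and 0.115. The oxidative stress list had a median of 0.16 over 41 transcripts (adjusted p = 0.0200) and the p53 and apoptosis list one of 0.17 over 45 (adjusted p = 0.0267), although the mean of the latter was -0.01. The exocrine pancreas and intestine list had a median of 0.12 and a mean of -0.03 over 41 transcripts (adjusted p = 0.523). Adjusted over the list alone, 3 of its transcripts were higher and 5 lower, with prss59 among the former and slc15a1a and the bile acid binding protein gene fabp6 (-0.70 ± 0.17) among the latter.

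The serotonin transporter genes, whose product is the target of fluoxetine, showed no detectable change at 47.2 µg/L, with log2 fold changes of 0.03 ± 0.44 for slc6a4a and 0.25 ± 0.21 for slc6a4b (SE; adjusted p of 1 and 0.842). The serotonin signalling list had a median of -0.06 over 29 transcripts (camera adjusted p = 0.822). In the stress axis list (median 0.12, 24 transcripts, adjusted p = 0.106), fkbp5, a glucocorticoid-responsive gene, had a log2 fold change of 1.77 ± 0.56 (SE; adjusted p = 0.279). The biotransformation list had a median of 0.08 (adjusted p = 0.822), with cyp1a at -0.09 ± 0.15, and the circadian clock list one of -0.14 (adjusted p = 0.0514), with per3 at -0.93 ± 0.30. In the neuropeptide list (median 0.05, adjusted p = 0.822), npvf, which encodes a hypothalamic RFamide peptide precursor, was lower when adjusted over the list alone (-1.62 ± 0.34), and its adjusted p over all transcripts was 0.0687. Medians were -0.04 for cholesterol biosynthesis (adjusted p = 0.749), 0.04 for lipid and energy metabolism (adjusted p = 0.862), 0.04 for the cell cycle (adjusted p = 0.854), -0.05 for estrogen and vitellogenesis (adjusted p = 0.853) and 0.08 for the thyroid axis (adjusted p = 0.822). Among cell type lists they were -0.11 for glia (adjusted p = 0.415), -0.01 for skeletal muscle (adjusted p = 0.822), -0.02 for cardiac muscle (adjusted p = 0.922), -0.02 for lens (adjusted p = 0.161), 0.03 for erythroid cells (adjusted p = 0.720) and 0.07 for epidermis (adjusted p = 0.144). Median and mean differed in sign for the cell cycle, thyroid, neuropeptide and erythroid lists, with means of -0.12, -0.30, -0.03 and -0.04.

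**Figure D1:**
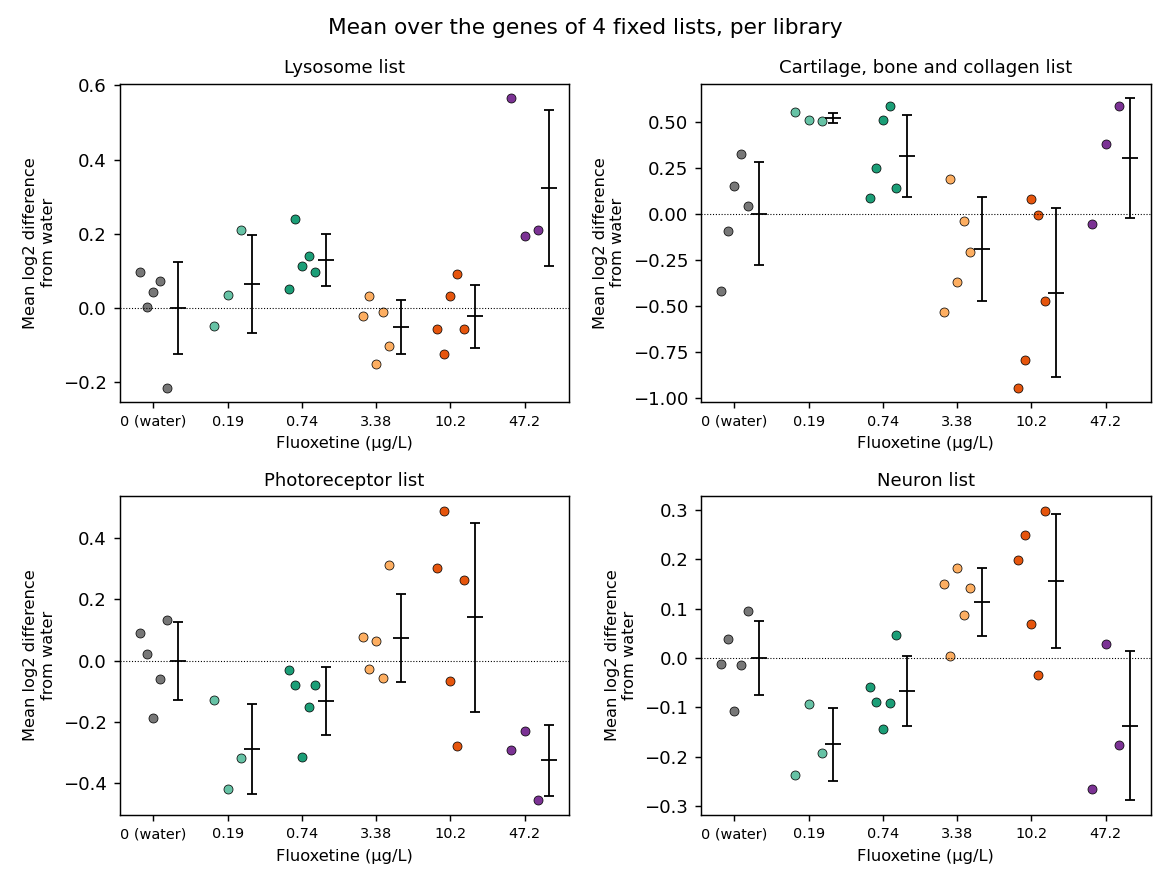
Mean log2 difference from the water mean over the genes of 4 fixed lists, for each of the 26 libraries (points) against fluoxetine concentration (µg/L), with the mean and SD of each group (bars). The lysosome list lies highest at 47.2 µg/L, with a mean of 0.32 and an SD of 0.21 over 3 libraries.

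At 0.74 µg/L, the largest rise among the called transcripts with a symbol and a mean of at least 1 CPM was that of glb1l2 (XM_039647641.1), a relative of beta-galactosidase. It rose from 5.09 ± 1.77 CPM (SD, n = 5) in water to 31.3 ± 7.29 CPM (SD, n = 5). Its log2 fold change was 2.62 ± 0.50 (SE; edgeR adjusted p = 0.0429). The complex I subunit ndufb5 rose by 1.42 ± 0.25, ktn1 by 1.3 ± 0.19, hpca by 1.13 ± 0.15 and anks1b by 0.86 ± 0.17 on the log2 scale (SE). The keratin krt97 rose by 0.53 ± 0.09. Among transcripts that fell were one of mbpa (-2.93 ± 0.48), one of the splicing regulator srek1 (-1.74 ± 0.30), that of the synaptic vesicle protein synpra (-0.90 ± 0.14) and that of the small GTPase rab28 (-0.59 ± 0.08). Summed over the transcripts of each gene, mbpa differed by 0.03 ± 0.11 (adjusted p = 0.991) and srek1 by -0.65 ± 0.16 (adjusted p = 0.115). The hpca and synpra calls held in all 26 fits that left out 1 library, the glb1l2 call in 8 of them and the anks1b call in 6. Those of ndufb5, krt97, srek1 and mbpa held in 20, 20, 19 and 24. In all, 39 transcripts were called, 24 higher and 15 lower. This count was 21, 15, 23, 19 and 16 without water replicates A to E in turn, and 12, 15, 18 and 17 without replicates A, B, D and E at 0.74 µg/L. It was 25 without replicate C at 3.38 µg/L and 25 without replicate B at 47.2 µg/L. When only the water and 0.74 µg/L libraries were fitted it was again 39, but 17 of these were among the first 39, and 30 were higher and 9 lower. It was 471 with DESeq2, 23 with no count filter, 24 without replicate B of both the 0.19 and 47.2 µg/L groups, and 1 with the fragment length of each library as a covariate. Adding the replicate letter as a block gave 103 calls, with 36 of the first 39 among them.

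Lists of structural and digestive tissues rose at 0.74 µg/L. The cartilage, bone and collagen list had a median log2 fold change of 0.28 (camera adjusted p = 1.32e-08) and the lens list one of 0.35 (adjusted p = 2.60e-05). Medians were 0.19 for the exocrine pancreas and intestine list (adjusted p = 8.80e-05) and 0.17 for the epidermis list (adjusted p = 0.000103). The biotransformation list (median 0.19, mean -0.05, adjusted p = 0.00803) and the lysosome list (median 0.13, adjusted p = 0.00346) rose as well, and the neuropeptide list fell (median -0.19, adjusted p = 0.00215). Each of these 7 calls had adjusted p = 0.641 with an estimated correlation, and the rise of the hepatocyte list (median 0.06, adjusted p = 0.0311) had adjusted p = 0.784 with an estimated correlation. In 4 of the 8 lists that passed at 0.74 µg/L, all 5 libraries lay on the side of the call. Over all transcripts tested, krt97 was called in the epidermis list. Adjusted over the list alone, 3 lens transcripts were higher, including that of the beaded filament protein bfsp2 (0.997 ± 0.26). In the biotransformation list, that of cyp3a65 (0.52 ± 0.14), a drug-metabolizing cytochrome P450, was higher by the same criterion. Without water replicate E the lysosome list did not pass (adjusted p = 0.0782), and with fragment length as a covariate the neuropeptide list passed in the opposite direction (adjusted p = 0.0319). Over all concentrations, 23 of the 41 list calls passed in the same direction with that covariate.

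At 0.19 µg/L, the lowest concentration, slc22a16 (XM_039693461.1) rose from 59.9 ± 4.23 CPM (SD, n = 5) in water to 107 ± 9.87 CPM (SD, n = 3). Its log2 fold change was 0.83 ± 0.07 (SE; edgeR adjusted p = 1.21e-06). The extracellular matrix gene fbln1 rose by 1.08 ± 0.19, ktn1 by 1.26 ± 0.21 and hpca by 1.07 ± 0.17 (log2, SE). The calcineurin regulator rcan1a fell by 0.62 ± 0.11 on the log2 scale and rab28 by 0.53 ± 0.09. The slc22a16 call held in all 26 fits that left out 1 library, those of fbln1 and rcan1a in 18, that of rab28 in 19, that of ktn1 in 20 and that of hpca in 21. All but the slc22a16 call were lost with fragment length as a covariate and without replicate B of both the 0.19 and 47.2 µg/L groups, and all 6 when only the water and 0.19 µg/L libraries were fitted. One transcript of the synaptic scaffold gene frmpd4 (XM_039671468.1) had a count of 0 in all 3 libraries against 14.98 ± 3.68 CPM (SD, n = 5) in water. This was at least 81.5-fold lower against a floor of 3 counts per library. The sum over the frmpd4 transcripts differed by -0.97 ± 0.26 (adjusted p = 0.188). In all, 22 transcripts were called, 10 higher and 12 lower. This count was 8, 6, 6, 7 and 12 without water replicates A to E in turn. Without replicates A, B and C at 0.19 µg/L there were 26, 15 and 24 calls, of which 11, 7 and 5 were among the 22. These were 8 higher and 18 lower, 5 and 10, and 3 and 21. Without replicate B of both the 0.19 and 47.2 µg/L groups, 5 of 17 calls were among the 22, and 4 were higher and 13 lower. The count was 610 with DESeq2, 3 with fragment length as a covariate and 2 when only the water and 0.19 µg/L libraries were fitted. Adding the replicate letter as a block gave 78 calls, with 21 of the 22 among them.

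The cartilage, bone and collagen list rose at 0.19 µg/L by a median of 0.50 over 63 transcripts (camera adjusted p = 2.78e-15; adjusted p = 0.641 with an estimated correlation). Adjusted over the list alone, 18 of its transcripts were higher, including those of osteopontin, spp1 (0.72 ± 0.17), and of the fin ray gene and3 (0.99 ± 0.24). For and3 the adjusted p over all transcripts was 0.171. The biotransformation list rose (median 0.17, mean -0.02, adjusted p = 0.0125), and the photoreceptor list (median -0.26, adjusted p = 3.07e-05) and the circadian clock list (median -0.22, adjusted p = 0.0379) fell, each with adjusted p = 0.641 with an estimated correlation. The epidermis list (median 0.18, adjusted p = 0.000438) and the exocrine pancreas and intestine list (median 0.14, adjusted p = 0.00158) rose and the neuron list fell (median -0.15, adjusted p = 0.00291), each with adjusted p = 0.664 with an estimated correlation. Skeletal muscle transcripts rose by a median of 0.10 (adjusted p = 0.00396; adjusted p = 0.741 with an estimated correlation), with the tropomyosin gene tpma (1.01 ± 0.21) higher when adjusted over the list alone. Neuropeptide transcripts fell by a median of 0.19 on the log2 scale (adjusted p = 0.0177; adjusted p = 0.774 with an estimated correlation).

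At 3.38 and 10.2 µg/L edgeR called 0 single transcripts (1829 and 2342 at an unadjusted p below 0.05) and DESeq2 called 87 and 107, and several lists moved against their direction at the lower concentrations. Cartilage, bone and collagen transcripts fell, with medians of -0.13 at 3.38 µg/L (camera adjusted p = 0.0170; adjusted p = 0.906 with an estimated correlation) and -0.33 at 10.2 µg/L (adjusted p = 2.72e-09; adjusted p = 0.641 with an estimated correlation). The epidermis list fell with medians of -0.23 and -0.24 (adjusted p = 8.15e-08 and 6.47e-07), and the immune list with medians of -0.14 and -0.16 (adjusted p = 0.00128 and 0.00920). The neuron list rose with medians of 0.11 and 0.16 (adjusted p = 0.000257 and 9.18e-07). All 6 had adjusted p = 0.641 with an estimated correlation. The photoreceptor list rose with medians of 0.11 and 0.23 (adjusted p = 0.0235 and 1.64e-06; adjusted p = 0.875 and 0.641 with an estimated correlation). The lens list rose with medians of 0.21 and 0.36 (adjusted p = 0.00803 and 6.09e-06; adjusted p = 0.857 and 0.641 with an estimated correlation). At 3.38 µg/L the cell cycle list rose (median 0.13, mean -0.01, adjusted p = 0.0256; adjusted p = 0.919 with an estimated correlation). There the hepatocyte list fell (median -0.05, adjusted p = 0.0365; adjusted p = 0.799 with an estimated correlation). At 10.2 µg/L the heat shock and unfolded protein list fell (median -0.14, adjusted p = 0.0227; adjusted p = 0.641 with an estimated correlation). Libraries of 1 group did not move alike, since all 5 lay on the side of the call in 1 of the 8 lists that passed at 3.38 µg/L and in 1 of the 7 at 10.2 µg/L.

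Among named genes at these concentrations, the clock-output gene tefb had a log2 fold change of -0.59 ± 0.17 at 10.2 µg/L and trh, the thyrotropin-releasing hormone gene, one of 0.61 ± 0.26 (SE), each with adjusted p = 0.925. Leaving out replicate C at 3.38 µg/L gave 1 call there, and leaving out replicates A and D at 10.2 µg/L gave 2 and 1. The median SE of a log2 fold change was 0.34 at each of these concentrations. On simulated counts for the 0.74 µg/L comparison, which also set 5 libraries against 5, the test recovered 4 of 50 transcripts changed 1.5-fold, 21 of 50 changed 2-fold, 28 of 50 changed 4-fold and 39 of 50 changed 8-fold. Most simulated changes of 1.5-fold and 2-fold were thus missed.

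Part of the calls at 0.19, 0.74 and 47.2 µg/L was shared. Of 18 transcripts called in at least 2 of these comparisons, 9 were called in all 3, including those of slc22a16, hpca, ktn1 and both transcripts of atp5mc3b, which encodes subunit c of the mitochondrial ATP synthase. The hpca transcript stood at 6.45 ± 1.05 CPM in water, 13.5 ± 0.811 at 0.19 µg/L, 14.2 ± 1.82 at 0.74 µg/L, 6.89 ± 1.44 at 3.38 µg/L, 6.65 ± 1.5 at 10.2 µg/L and 13.6 ± 0.399 at 47.2 µg/L (SD). The actin-binding gene lasp1 and the zinc finger gene zfand3, named after their values had been seen, were also called at all 3 concentrations, by 0.49 ± 0.07 and 0.37 ± 0.06 at 47.2 µg/L (log2, SE). The transcripts of atp5mc3b moved in opposite directions, XM_039689574.1 with log2 fold changes of 0.71, 0.59 and 0.49 and XM_039689575.1 with -0.62, -0.64 and -0.64 at 0.19, 0.74 and 47.2 µg/L. Their sum differed from water by 0.10 ± 0.08, 0.02 ± 0.07 and -0.04 ± 0.08 (SE), with adjusted p of at least 0.696. With their direction at the called concentrations taken as positive, the 18 transcripts had median log2 fold changes of 0.70, 0.62, -0.04, -0.06 and 0.70 from 0.19 to 47.2 µg/L. Overlaps of calls were 8 higher and 5 lower between 0.19 and 0.74 µg/L, 6 and 4 between 0.19 and 47.2 µg/L, and 8 and 5 between 0.74 and 47.2 µg/L. Independent lists would share at most 0.0175, but all comparisons used the same water libraries, so these lists were not independent. With the water libraries split between the comparisons, which leaves fewer libraries and fewer calls (means of 5.75, 9.7 and 7.35), the overlaps fell to means of 2.35, 1.15 and 1.5 over 10 splits. Independent lists in these splits would share means of 0.000635, 0.00049 and 0.000785.

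**Figure D2:**
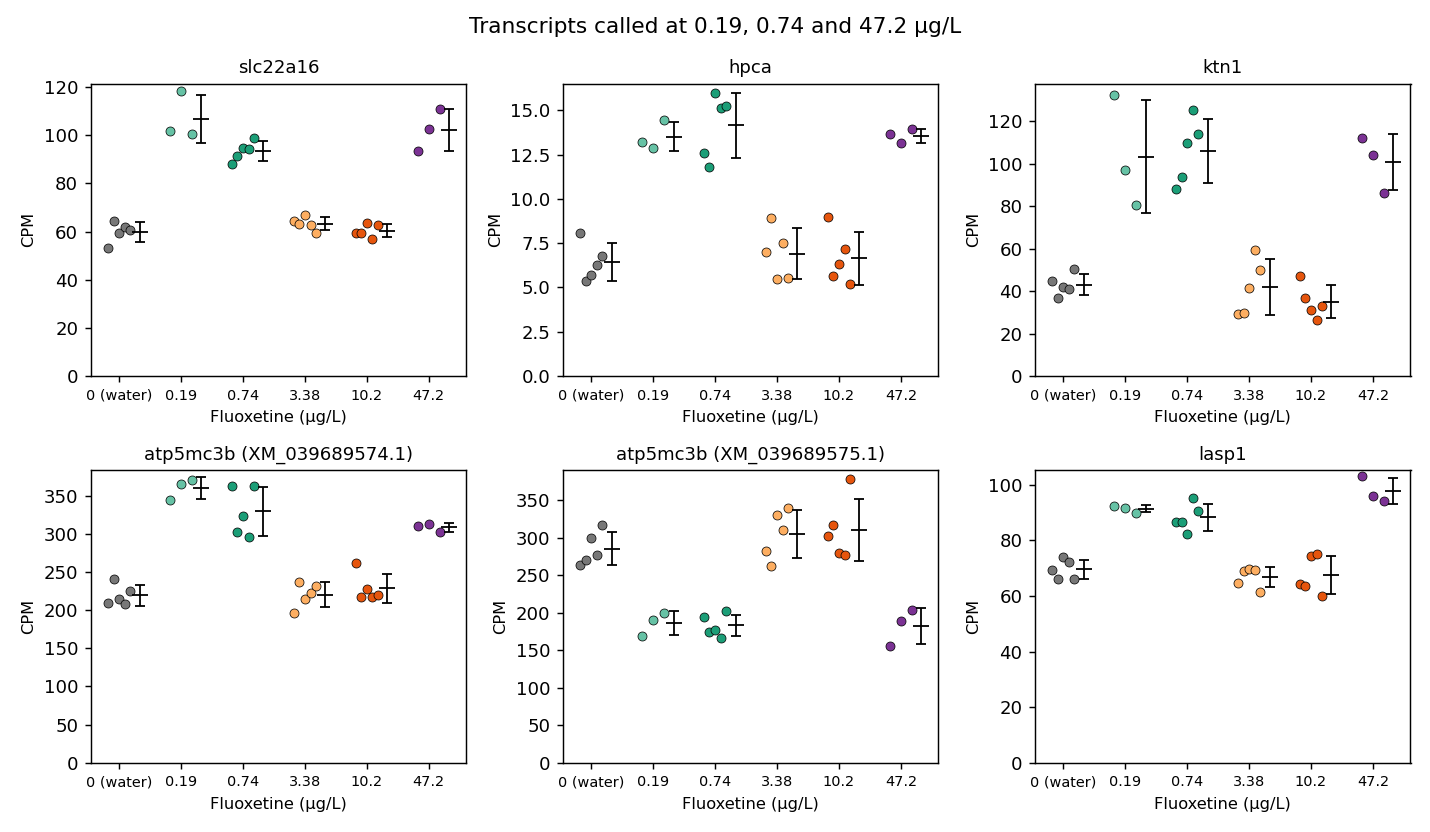
CPM in each library (points) for 6 transcripts called at 0.19, 0.74 and 47.2 µg/L, against fluoxetine concentration (µg/L), with the mean and SD of each group (bars). For slc22a16 the libraries at these 3 concentrations all lie above those of water, 3.38 and 10.2 µg/L, and the 2 atp5mc3b transcripts move in opposite directions.

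Comparisons between each pair of groups fell along the same line. The 9 pairs that set 0.19, 0.74 or 47.2 µg/L against water, 3.38 or 10.2 µg/L had between 22 and 940 calls (median 545), and the 6 pairs within either side had between 0 and 6. Of the 9, those with water had the fewest, 22, 39 and 45, and those with 3.38 or 10.2 µg/L had between 239 and 940. Water thus differed less from 0.19, 0.74 and 47.2 µg/L than 3.38 and 10.2 µg/L did, by number of calls. Between 0.19 and 0.74 µg/L, and between 3.38 and 10.2 µg/L, edgeR called 0 transcripts (1810 and 1224 at an unadjusted p below 0.05; DESeq2 was not run on these pairs). The contrast of 0.19, 0.74 and 47.2 µg/L together against 3.38 and 10.2 µg/L, which holds no water library and was added after seeing the data, had 5978 calls, 3141 higher and 2837 lower. In it ktn1 stood at 1.43 and slc22a16 at 0.70 (log2). Because every comparison used the same water libraries, correlations of fold changes were set against simulated unchanged groups. Across 35197 transcripts of at least 1 CPM, which are not independent replicates, r was 0.492, 0.505 and 0.5003 among comparisons 0.19 with 0.74, 0.19 with 47.2 and 0.74 with 47.2 µg/L. It was 0.431, 0.375 and 0.435 for unchanged groups (20 simulations), and 0.0988, 0.156 and 0.0903 with the water libraries split between the comparisons. The covariance of fold changes exceeded the simulated one by 0.0822, 0.140 and 0.0718, and for 3.38 with 10.2 µg/L by 0.0412. For the 6 pairs between the sides it lay below the simulated one, with differences from -0.0588 to -0.0430.

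**Figure D3:**
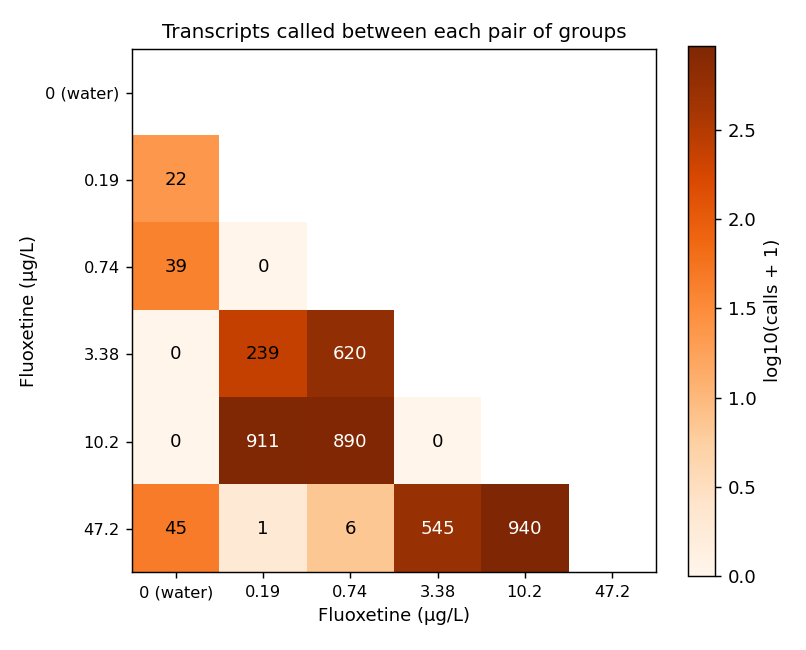
Number of transcripts called by edgeR at an adjusted p below 0.05 between each pair of the 6 groups, by fluoxetine concentration (µg/L) on both axes, with colour on a log10 scale of calls plus 1. Pairs within water, 3.38 and 10.2 µg/L have 0 calls, and pairs that set these against 0.19, 0.74 and 47.2 µg/L have 22 to 940. Of the latter, those with water have 22, 39 and 45.

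A test of any difference among the 6 groups called 1190 transcripts, 802 of them with a symbol, with slc22a16 at the smallest adjusted p (2.96e-08). This count was 792 and 779 without replicates B and D at 0.74 µg/L, 792 and 764 without replicates C and E at 3.38 µg/L, and 743, 714, 2008 and 762 without replicates A, B, D and E at 10.2 µg/L. It was 4639 with DESeq2, 2005 with gene sums, 2730 with the replicate letter as a block and 21 with fragment length as a covariate.

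A test for a slope on concentration called few transcripts, and as many calls can arise by chance. Of 100 splits of the libraries, the real one among them, 53 gave at least 6 calls. The transcript of tspan34a (XM_039647877.1), a tetraspanin membrane protein gene, rose by 0.11 ± 0.02 (log2, SE) for each doubling of the concentration plus 0.1 µg/L. Its edgeR adjusted p was 0.0373. This call held in 15 of the 26 fits that left out 1 library. It was lost with a strict count filter, the replicate letter as a block, fragment length as a covariate or a slope on ranks. It was also lost without the 47.2 µg/L group or replicate B of both the 0.19 and 47.2 µg/L groups. The tspan34a transcript rose from 27.3 ± 5.41 CPM (SD, n = 5) in water through 36.9 ± 8.58 at 3.38 µg/L and 42.7 ± 8.21 at 10.2 µg/L to 54.8 ± 16.2 CPM (SD, n = 3) at 47.2 µg/L. The collagen transcript col8a1b fell with concentration, at a mean of 0.102 CPM over all libraries, which is below the level of 3 counts in every library. Its call held in 10 of the 24 fits without 1 library that tested it. The other 4 of the 6 calls (3 higher and 3 lower) carried no symbol and had group means of at most 2.63 CPM. Of these, XM_039652078.1, called higher, stood at 1.59 CPM at 10.2 µg/L and 0.439 CPM at 47.2 µg/L. The trend test made 0 calls without water replicates A or C, replicate C at 0.74 µg/L, replicates B, C or E at 3.38 µg/L, or replicates D or E at 10.2 µg/L, and 3 and 1 without water replicates B and D. It made 14 and 11 calls without replicates B and C at 0.19 µg/L, 10 without replicate A at 10.2 µg/L and 17, 19 and 10 without replicates A, B and C at 47.2 µg/L. All 26 libraries gave 1300 at an unadjusted p below 0.05, and DESeq2 called 10, of which 1 was among the 6 of edgeR. With fragment length as a covariate there were again 6 calls, 2 of them among the first 6. The edgeR count was 92 with no count filter, 0 with a strict one (1008 at an unadjusted p below 0.05), 1 with a slope on ranks and 0 without the 47.2 µg/L group (4339 at an unadjusted p below 0.05). With the replicate letter as a block it was 0 (1800 at an unadjusted p below 0.05).

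Benchmark concentrations, at which a fitted curve had moved by 1 residual SD from its control value, were obtained for 1841 of the 2852 transcripts past the prefilter. Their 10th percentile was 0.444 µg/L (95% bootstrap interval 0.312 to 0.588), the 20th lowest 0.0434 µg/L (0.0396 to 0.0486) and the median 14.1 µg/L (8.65 to 19.3). These intervals treat transcripts as independent and leave out the spread between libraries. The 20th lowest lies below 0.19 µg/L, the lowest concentration tested, where only water was measured. It therefore depends on the assumed curve shapes and on the smallest constant allowed in them, and its narrow interval does not measure its precision. Random splits of the libraries put a median of 1470 transcripts past the same prefilter (highest 2873), so many of the values may be chance. Among fixed lists, 12 of 72 lysosomal transcripts had a value, with a median of 36.4 µg/L and a range from 18.03 to 41.0 µg/L. Medians were 39.5 µg/L for 6 photoreceptor transcripts, 25.6 µg/L for 12 circadian clock transcripts, 12.1 µg/L for 10 exocrine pancreas and intestine transcripts, 2.88 µg/L for 16 cartilage, bone and collagen transcripts and 2.37 µg/L for 4 neuronal transcripts. The value for tspan34a was 3.09 µg/L. Of all values, 141 lay below 0.19 µg/L, the lowest concentration tested, 81 between 0.19 and 0.74, 423 between 0.74 and 3.38, 254 between 3.38 and 10.2 and 942 between 10.2 and 47.2 µg/L.

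The curves do not return towards the control level, so transcripts such as hpca, raised at 0.19, 0.74 and 47.2 µg/L but not between, are not described by them. Nor can they follow a change of direction. From 0.19 to 47.2 µg/L the cartilage, bone and collagen list had median log2 fold changes of 0.50, 0.28, -0.13, -0.33 and 0.40. The neuron list had -0.15, -0.08, 0.11, 0.16 and -0.18. The median benchmarks of these lists therefore do not give the concentration at which the lists began to change. The 10th percentile was 0.252 µg/L without water replicate A, 0.249 and 0.302 without replicates C and E at 3.38 µg/L, 0.243, 0.183 and 0.284 without replicates A, B and E at 10.2 µg/L, and 0.705 and 0.619 without replicates B and C at 47.2 µg/L. It was 1.91 µg/L with an adjusted prefilter, 20.1 µg/L with linear curves alone and 0.675 µg/L without replicate B of both the 0.19 and 47.2 µg/L groups. The median was between 4.71 and 7.49 µg/L without water replicate A, B or E, replicate B at 3.38 µg/L, replicate C or D at 10.2 µg/L, or replicate A or C at 47.2 µg/L. It was between 21.6 and 22.2 µg/L without replicate A, B or C at 0.19 µg/L or replicate B at 0.74 µg/L. It was 36.0 µg/L with an adjusted prefilter, 32.2 µg/L with linear curves alone, 8.73 µg/L with the SD of the water libraries, 22.0 µg/L without replicate B of both the 0.19 and 47.2 µg/L groups and 3.73 µg/L without the 47.2 µg/L group. The 20th lowest was 0.0973 µg/L with an adjusted prefilter, 14.9 µg/L with linear curves alone and 0.0282 µg/L with the SD of the water libraries, and the first of these settings gave 981 values and the second 941.

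**Figure D4:**
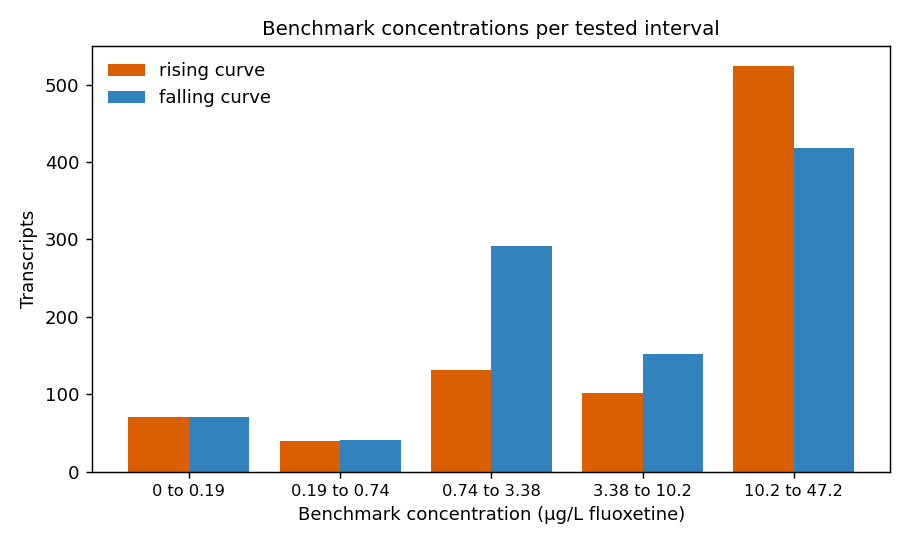
Number of transcripts (vertical axis) whose benchmark concentration lies in each interval between tested concentrations (horizontal axis, µg/L fluoxetine), with rising and falling curves as separate bars. The interval from 10.2 to 47.2 µg/L holds 942 of the 1841 transcripts, 524 rising and 418 falling.

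The authors' deposited table gave 472 calls at 0.19 µg/L, 400 at 0.74, 18 at 3.38, 24 at 10.2 and 671 at 47.2 µg/L at an adjusted p below 0.05, among 26962 transcripts per comparison. All 21, 38 and 43 edgeR calls that fell among those transcripts at 0.19, 0.74 and 47.2 µg/L, ctsla and slc15a1a among them, were also called in the authors' deposited table. Log2 fold changes from edgeR and from the authors' deposited table correlated across transcripts with r from 0.889 to 0.910, and from 0.999 upwards where the deposited value lay within 5 of 0. In the authors' deposited table, 45, 23, 10, 10 and 34 of the calls from 0.19 to 47.2 µg/L had a log2 fold change beyond 15 in either direction.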

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

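Of the tests in this part, those of fragment length, of a steady rise with concentration, of the exposure at 47.2 µg/L and of the lysosome list against 0.19 and 0.74 µg/L without each library were chosen only after the result was seen.

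In groups of 5 libraries, 169 sets of values were searched for a library whose gap to the nearest other exceeded 0.71 of the range. Chance gives about 1 in 20, which is 8.45 here, and 11 were found. Replicate A at 3.38 µg/L had a fragment length of 222 bp against 237 to 242 bp (gap 0.732 of the range), and replicate C at 10.2 µg/L one of 247 bp against 226 to 230.2 bp (0.802). The others were water libraries, with levels in log2 CPM. Replicate C had aqp8a.1 at 6.41 against 6.65 to 6.73 (0.733) and nr1d2a at 3.86 against 2.52 to 2.86 (0.744). Replicate A had kif11 at 2.48 against -3.18 to -2.57 (0.893), esr2a at 1.31 against -3.18 in each other library (1), pnoca at 3.41 against 3.75 to 3.81 (0.839) and cyp7a1 at 5.19 against 5.63 to 5.80 (0.721). Replicate E had pola1 at 2.94 against -3.18 in each other library (1), replicate D had trh at 0.70 against 1.75 to 1.97 (0.828), and replicate B had glulb at 7.94 against 7.65 to 7.72 (0.777).

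At 0.19, 0.74 and 47.2 µg/L, 18 transcripts were called in at least 2 of the comparisons with water, 9 of them, such as slc22a16 and hpca, in all 3, and edgeR called 0 transcripts at 3.38 and 10.2 µg/L (1829 and 2342 at an unadjusted p below 0.05, 87 and 107 with DESeq2). Water libraries that stand apart cannot be the whole cause, since the median difference was 0.60 in a contrast without water, and a steady rise with concentration is argued against by a median of -0.0585 at 10.2 µg/L. Fragment length is argued against at 47.2 µg/L, where 2 of 3 libraries lay within the 222 to 247 bp of the water, 3.38 and 10.2 µg/L libraries. At 0.74 µg/L a linear covariate left the median at 0.58 (from 0.62), while calls among the 18 fell from 17 to 1. The SE of a single transcript, as the median over the 18, grew from 0.0943 to 0.142. At 0.19 and 0.74 µg/L no library lay within that range, so this correction is extrapolated and cannot decide whether fragment length is the cause there. How to read it was settled after its value was seen. Over all transcripts, the covariate took calls from 22 to 3 at 0.19, from 39 to 1 at 0.74 and from 45 to 34 at 47.2 µg/L. A batch of embryos or libraries shared by 0.19, 0.74 and 47.2 µg/L may be the cause and cannot be told apart from the groups, since the labels give no batch and the median number of calls within a side was 0, and a response that is not monotonic stays open, untested.

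In the authors' deposited table, 122 calls (81 distinct transcripts, 27 higher and 95 lower) had a log2 fold change beyond 15, and edgeR, at its adjusted threshold, called 0 of them. All of them, 100%, switched between under 1 and over 10 counts within a group outside the comparison. Of 18659 other transcripts in the authors' deposited table with a mean count in the same range, 23.9% did so in some exposure group. The latter were not chosen for a whole group near 0, as the 122 calls in effect were, so the shares are not directly comparable. Such switching is a candidate explanation. Reads moving between transcripts of 1 gene stay open: the 50 with another tested transcript had a median absolute change of 0.11 in the gene sum, but 50 of 122 are too few to decide. No biological explanation was tested.

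The lysosome list rose at 47.2 µg/L, most in replicate A (0.566 above the water mean, against 0.195 and 0.209). A single library is argued against as the whole cause by p of at most 2.59e-06 without any 1 of the 3 (camera, preset correlation, and 0.0375 with an estimated one), but the median fell from 0.30 to 0.19 without A. More lysosome-rich enterocytes are argued against by a median of -0.56 over 9 uptake marker transcripts, 0 of them called. This holds only if expression per cell did not fall, which was not tested. Of the 7 marker genes, 5 are also on the exocrine pancreas and intestine list. The most abundant, fabp6 (227 CPM) and tm4sf4 (184 CPM), stood at -0.70 and -0.41, while lrp2b stood at -0.74 and lrp2a at 0.06. The difference shared with 0.19 and 0.74 µg/L stays open: p was 4.72e-11 for 47.2 against those groups (0.0120 estimated), under the bound of 0.05 set beforehand, but without A the median was 0.10 and p 0.00472 (0.195 estimated), and since the estimated correlation, 0.123, exceeds the preset 0.01, that bound was too lenient, a reading settled after these values were seen. More macrophages in the pools may contribute. Their markers had a median of 0.38 against 0.30 for the list, and 0 of their 17 genes are on the lysosome list and 2 on the immune list. However, apoc1, the most abundant at 274 CPM, stood at -0.39 and coro1a (29.9 CPM) at 0.36. The markers had medians of 0.29, 0.15, -0.20 and -0.18 from 0.19 to 10.2 µg/L, so their rise was not particular to 47.2 µg/L. At 0.19 µg/L the lysosome list had a median of 0.08. The exposure itself may also be the cause, with medians of at most 0.13 in the other exposure groups, although without A the list did not reach the ratio of 2 over them that was asked for. Since the shared difference and cell make-up stay open, and these explanations are not exclusive, the rise is not ascribed to the exposure.

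Other splits of the same libraries were counted for each number of calls. Chance is argued against at 0.19 µg/L, where 1 of 56 splits, the real one, gave as many as the 22 calls (highest other 3). So it is at 0.74 µg/L (39 calls, 1 of 100 splits, highest other 1), at 47.2 µg/L (45, 1 of 56, highest other 2) and for any difference (1190, 1 of 100, highest other 3). A share of 1 in 56 is the smallest that those splits can give, so chance is not ruled out. For the trend it cannot be excluded (6 calls, 53 of 100 splits, highest other 17). At 3.38 and 10.2 µg/L edgeR called 0 (1829 and 2342 at an unadjusted p below 0.05, 87 and 107 with DESeq2), so all 100 splits gave as many by construction (highest other 2), and the splits say nothing there. For the benchmark prefilter (2852 transcripts), 2 of 100 splits, the real one among them, gave as many, which is under the share set beforehand. The highest other split gave 2873, however, and the median other 1470. Chance is thus not excluded for these transcripts, since random splits also passed many.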

How the results depend on the processing

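In this part, fragment length as a covariate, sums per gene and the fit without replicate B of both the 0.19 and 47.2 µg/L groups were chosen only after seeing the data; the cause of a change was not tested unless given. RLE size factors kept each count of calls within 1.5 times and shifted the median of all transcripts by at most 0.0035 (log2). Of 337 values of named transcripts under other settings, 253 kept direction and side of the threshold, 82 were no longer past it, 2 moved and 0 reversed.

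DESeq2 called 610, 471, 87, 107 and 783 transcripts from 0.19 to 47.2 µg/L, 4639 for any difference and 10 for trend, and its calls held all 22, 39 and 45 edgeR calls at 0.19, 0.74 and 47.2 µg/L and 1180 of 1190 for any difference, but 1 of 6 for trend. Without a count filter there were 23 at 0.74, 29 at 47.2 and 92 for trend, and a strict filter gave 0 for trend (edgeR, 1008 at an unadjusted p below 0.05). Fits of only 2 groups, which have fewer libraries, gave 2 at 0.19, 39 at 0.74 (17 of them among the first 39) and 0 by edgeR at 47.2 µg/L (3258 unadjusted). The fragment length covariate gave 3 at 0.19, 1 at 0.74 and 21 for any difference, left 25 list calls, and reversed the neuropeptide list at 0.74 µg/L (adjusted p = 0.0319). Sums per gene gave 101 at 47.2 and 2005 for any difference. Without replicate B of both groups there were 24 at 0.74 and 17 for trend, and of the calls at 47.2 µg/L 43.1% were higher. The slope on ranks gave 1 and the trend without 47.2 µg/L 0 (4339 unadjusted). With an estimated correlation 0 list tests passed, and with fry 0, against 41.

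The replicate letters were not taken to pair the libraries, since the labels give no meaning to them. The mean correlation of same-letter deviations was 0.0521 and the lowest -0.0232, where 0.1 was needed in every pair. However, 25 of 26 libraries were closest to their own letter. Means were 0.0650 to 0.0800 in each pair of groups among water, 0.74, 3.38 and 10.2 µg/L. The mean was 0.104 between 0.19 and 47.2 µg/L, and 0.00576 to 0.0490 in pairs across these sets. A factor shared by libraries of 1 letter within each set thus stays open, and the main tests left it out. Here 0.74 µg/L fell with water, 3.38 and 10.2 µg/L, unlike in the calls. With the letter as a block, calls were 78, 103 and 182 at 0.19, 0.74 and 47.2 µg/L, 2730 for any difference and 0 for trend (1800 unadjusted), and 8 more list tests passed and 1 fewer.

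For benchmark concentrations, an adjusted prefilter gave 1195 transcripts past it, 981 values, a 10th percentile of 1.91, a 20th lowest of 0.0973 and a median of 36.0 µg/L. Linear curves alone gave 941 values, 20.1, 14.9 and 32.2 µg/L. The SD of the water libraries gave a 20th lowest of 0.0282 and a median of 8.73, the fit without replicate B of both groups a 10th percentile of 0.675 and a median of 22.0, and leaving out 47.2 µg/L a median of 3.73 µg/L.

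Leaving out each library in turn gave 6 to 26 calls at 0.19, 12 to 43 at 0.74, 0 to 1 at 3.38, 0 to 2 at 10.2 and 8 to 62 at 47.2 µg/L, 714 to 2008 for any difference, 0 to 19 for trend and 36 to 46 list tests. The 10th percentile of benchmarks ran from 0.183 to 0.705, the 20th lowest from 0.0354 to 0.0449 and the median from 4.71 to 22.2 µg/L, over 1665 to 2428 values and 2639 to 3323 transcripts past the prefilter. The narrow range of the 20th lowest lies wholly below the lowest concentration tested, where the curve shapes and not the libraries set the values. Depth was 13515500 to 27615000 counts. In simulated counts, 4% of 1.5-fold changes were recovered at 47.2 µg/L (3 libraries) and 8% at 0.74 µg/L (5 libraries). Neither depth nor the number of libraries was varied alone, so what limits small changes was not tested.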

Other observations

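The contrast in this part was chosen only after the data had been seen. Set against the mean of 0.19 and 0.74 µg/L, the groups that 47.2 µg/L resembled most, heat shock and unfolded protein transcripts were higher at 47.2 µg/L by a median of 0.24 (camera, adjusted p = 1.45e-07; adjusted p = 0.0761 with an estimated correlation). Immune transcripts were higher by 0.23 (adjusted p = 3.08e-05) and p53 and apoptosis transcripts by 0.16 (adjusted p = 0.000747), each with adjusted p = 0.0761 with an estimated correlation. Hepatocyte transcripts had a median of -0.19 (adjusted p = 1.32e-09; adjusted p = 0.0761 with an estimated correlation), exocrine pancreas and intestine transcripts one of -0.15 (adjusted p = 2.18e-07; adjusted p = 0.233 with an estimated correlation) and lens transcripts one of -0.19 (adjusted p = 1.80e-05; adjusted p = 0.415 with an estimated correlation). Markers of uptake in lysosome-rich enterocytes, cells that take up protein from the gut lumen, included lrp2b (-0.74 ± 0.23, log2, SE) and the intrinsic factor receptor gene cubn (-0.56 ± 0.25) at 47.2 µg/L against water, with adjusted p of 0.185 and 0.383 in edgeR. The list's median was -0.0036 at 0.19 µg/L, 0.25 at 0.74 µg/L, -0.00016 at 3.38 µg/L and 0.08 at 10.2 µg/L.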
